A study of Mus musculus with 10 samples.

How the data were processed

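Round spermatids, the haploid germ cells formed by meiosis, were studied after a short heating of the testis. Per the labels, adult male CD1 mice, an outbred stock, were kept under isoflurane while the testes lay against water at 33 °C (control) or 42 °C (heat) for 30 minutes. The mice woke up and were then killed at once for the isolation of the cells. Each group had 5 mice and 1 library per mouse, so 10 libraries were compared. The p-values of single features and of shares of counts measure the spread between these mice. Total RNA was depleted of ribosomal RNA and made into stranded libraries, per the labels. The values thus describe RNA after the recovery from anaesthesia and the isolation of the cells, and the time taken by the isolation was not taken into account. Small RNAs were not analysed here.

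The authors deposited 1 table of raw read counts, with no normalization, for 55401 genes and 1146 subfamilies of transposable elements (TE). That the values are counts was judged from the table itself, since all are whole numbers and their sums differ between libraries. The submitters' processing notes name Trim Galore, cutadapt and DRAGEN and the builds GRCm38 and mm10, with no versions and no roles. The counting tool, the strand setting of the counting and the treatment of reads with several alignments are not given in the sources used here. A TE subfamily is a sum over many genomic copies, so its count depends on how such reads were shared out. A TE inside an intron or past a gene can also be counted from the RNA of that gene. Gene positions in the table were compared with the GENCODE M21 annotation of GRCm38. Of 55141 shared identifiers, 99.4% had the same chromosome, start, end and strand. Total counts per library ran from 60623568 (42 °C replicate 2) to 117723075 (33 °C replicate 2). No pair of libraries within a group was alike within sampling noise. The closest pair, 42 °C replicates 1 and 3, had a chi-square per degree of freedom of 15.7 over genes and TE subfamilies together. Every other pair within a group had 60.3 or more.

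The counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the group as the sole term. TMM factors were computed over genes and TE subfamilies together. Features were kept by filterByExpr with a minimum count of 10, a minimum total of 15 and a smallest group of 5. This left 26025 features, of which 24948 were genes and 1077 were TE subfamilies. Adjusted p-values are Benjamini-Hochberg values over all 26025, and the threshold was 0.05. Levels are CPM, computed by edgeR from the deposited counts with TMM-scaled library sizes, given as mean ± SD with n = 5 per group. Log2 fold changes are 42 °C minus 33 °C, with the standard error (SE) of the edgeR fit. The share of each library's counts on TE, and on 8 parts of them, was compared with an exact two-sided permutation test over all 252 assignments of the libraries, whose smallest possible p is 0.00794. Intervals for shares of genes are exact binomial ones at 95%, and they cover counting error only.

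The design, the alternatives, the rule for named genes and 40 lists were fixed before the data were examined. Lists with at least 3 tested members were tested against all other features with camera of limma 3.58.1, at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. At the preset correlation the members count as nearly independent, so these p-values do not measure the spread between mice. The estimated correlation ran from -0.015 for p53 targets to 0.998 for B4 SINEs, with 0.950 for the L1 family. The 27 gene lists were heat shock chaperones, testis-enriched chaperones, immediate-early genes, the piRNA pathway, chromatin and RNA repressors of TE, the unfolded protein response, antioxidant and metal response, p53 targets, apoptosis machinery, interferon and nucleic acid sensing, SR splicing factors and CLK kinases, RNA granule proteins, proteasome subunits, cytosolic ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, and markers of round spermatids, elongating spermatids, spermatocytes, spermatogonia, Sertoli cells, Leydig cells, peritubular and stromal cells, macrophages and leukocytes, endothelium and erythroid cells. The 13 TE lists were young L1, IAP, ETn and MusD, MERVL, L1, ERVK, ERVL with ERVL-MaLR, ERV1, B1, B2 and B4 SINEs, DNA transposons and satellites.

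Genes were named by this rule. Part 1 took the 10 genes with the largest change in each direction that passed the threshold, had a mean of at least 1 CPM and a given gene symbol, and had all 5 libraries of a group on one side of the other group's mean. Part 2 took Hspa1a, Hspa1b, Hsph1, Dnajb1, Hspa8, Piwil1, Piwil2, Mael, Mov10l1 and Tdrd1 whatever their result. Part 3 took up to 4 members of smallest p from each list that was called or had a member past the threshold, and 1 member of any other list. Part 4 took the 5 TE subfamilies of smallest p in each direction and the 6 young L1 subfamilies. Part 1 gave 3 genes, so the other genes past the threshold were named after their values were seen, as was the sum of Hspa1a and Hspa1b.

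The alternatives were other scalings, DESeq2 1.42.0, limma voom with quality weights, other filters on low counts, a block on the replicate number, a minimum fold of 1.2 and leaving out each library in turn. Further ones were added after the data were seen and are listed with the effects of all of them in the closing section. The tests were tried on simulated counts for the comparison of 42 °C with 33 °C, drawn over 24948 genes with 50 genes changed at each fold. All changed features had a mean of at least 1 CPM, so the rates do not cover lower levels, where 19 of the 24 called genes lay. Counts were drawn feature by feature from the spread fitted by edgeR. Structure shared by samples is thus absent, and the comparison of tools may favour edgeR. edgeR recovered 64.0% of genes raised 2 times, 100.0% of genes raised 4 times, 38.0% of genes lowered to 0.5 and 96.0% of genes lowered to 0.25. For 20 TE subfamilies each it recovered 15.0% of those raised 1.5 times and 35.0% of those raised 2 times. Of its 165 calls 3.64% were false, against 25.7% of 261 calls by DESeq2 and 3.61% of 166 calls by limma voom. Where no gene was changed, edgeR made 0 calls, limma voom 0 and DESeq2 18.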

Results

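RNA from round spermatids of 10 mice was compared, 5 with testes held at 33 °C and 5 at 42 °C for 30 minutes. The comparison asks how a short heating of the testis changes the transcripts of these cells, with the piRNA pathway and LINE1 (L1) elements named in the title of the study. Total counts per library were between 92311183 and 117723075 at 33 °C and between 60623568 and 102086073 at 42 °C. The library of lowest depth, 42 °C replicate 2, was also the one with the largest share of counts on TE.

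A small set of genes, most of them close to silent at 33 °C, rose at 42 °C. Hspa1a, which encodes the inducible HSP70 chaperone (ENSMUSG00000091971, chromosome 17, 34969190 to 34972156, GRCm38), rose 7.66-fold, from 0.278 ± 0.0987 CPM at 33 °C to 2.14 ± 1.04 CPM at 42 °C (SD, n = 5 each). Dpys, which encodes dihydropyrimidinase, an enzyme of pyrimidine breakdown (chromosome 15, 39768487 to 39857470), rose from 0.0120 ± 0.0220 CPM to 1.31 ± 0.0953 CPM, from 6 to 598 counts per group. The processed pseudogene 4930555K19Rik (chromosome 15, 41173487 to 41173868) had 0 counts in all 5 libraries at 33 °C, and 972 counts at 42 °C (2.10 ± 0.476 CPM). Stat2, a transcription factor of interferon signalling (chromosome 10, 128270559 to 128292849), fell from 24.5 ± 20.4 CPM to 0.833 ± 0.143 CPM. The long noncoding RNA Slmapos2 (chromosome 14, 26389199 to 26395521) rose 1.99-fold, from 1.57 ± 0.200 CPM to 3.11 ± 0.307 CPM.

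**Figure D1:**
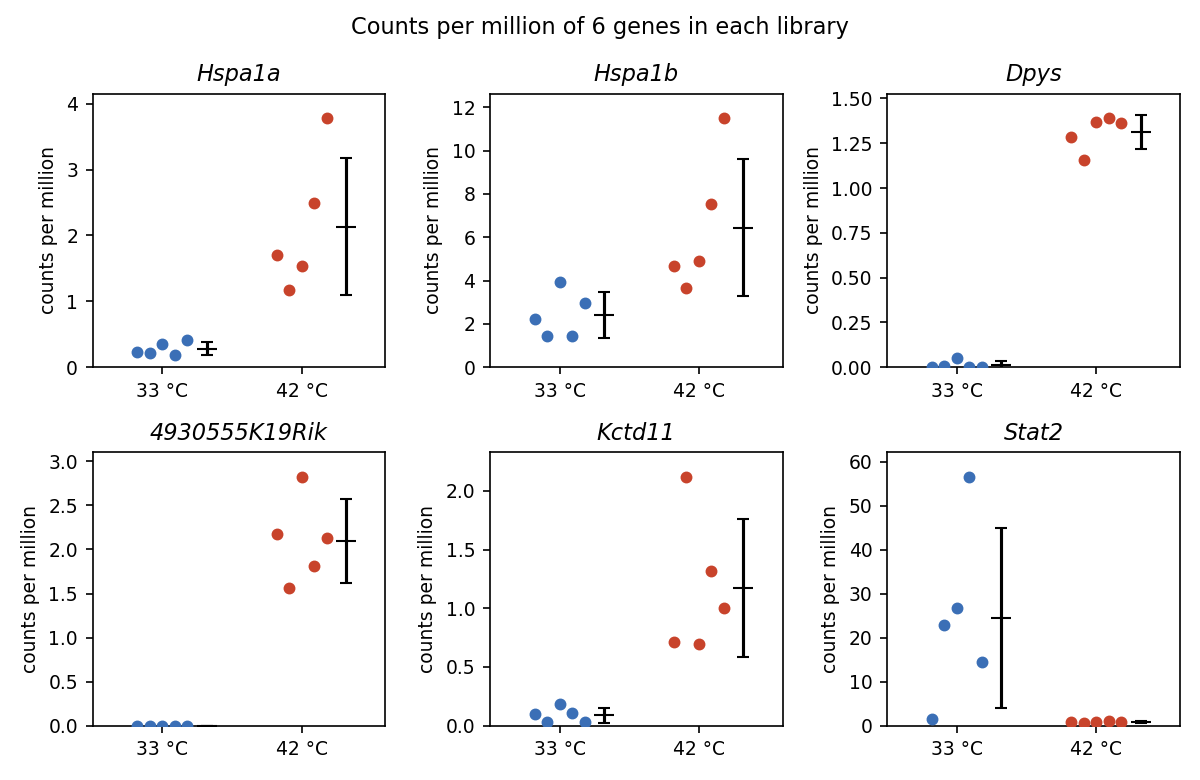
CPM (linear axis from 0) of Hspa1a, Hspa1b, Dpys, 4930555K19Rik, Kctd11 and Stat2 in the 5 libraries at 33 °C and the 5 at 42 °C. Points are libraries, and the bar beside them is the mean ± SD. Hspa1a lay between 0.181 and 0.417 at 33 °C and between 1.17 and 3.78 at 42 °C, and Stat2 between 1.42 and 56.6 at 33 °C and between 0.667 and 1.03 at 42 °C.

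Of the genes past the test, those named here other than Hspa1a, Stat2 and Slmapos2 were chosen after their values were seen. In the edgeR quasi-likelihood test 23 genes were higher at 42 °C and 1 was lower at an adjusted p of 0.05. At an unadjusted p under 0.05 the counts were 2198 higher and 764 lower. Hspa1a had a log2 fold change of 2.94 (SE 0.36, edgeR adjusted p = 0.0106), Dpys of 6.58 (SE 0.58, edgeR adjusted p = 0.000887; 8.38 without 33 °C replicate 3, which holds 5 of its 6 counts at 33 °C) and Stat2 of -4.87 (SE 0.71, edgeR adjusted p = 0.0278). For Slmapos2 the value was 0.99 (SE 0.16, edgeR adjusted p = 0.0383). Lrrc14b rose by 3.23 on the log2 scale, Apol9a by 3.50, Zpld2 by 3.65 (4.28 without 33 °C replicate 3), Naprt, an enzyme of NAD synthesis, by 2.63, Chrna10, a subunit of nicotinic acetylcholine receptors, by 2.45, Adprhl2, an ADP-ribose hydrolase, by 1.66, and Gm13333 from 3 to 97 counts per group. These 7 genes, Hspa1a, Dpys and 4930555K19Rik were the 10 called in each of the 10 fits that left out 1 library. Prdm14, a regulator of germ cell formation (log2 3.02), and Kctd11 (log2 3.68) were called in 8 of those fits, and Dnase2a, Ajm1, Dpep2, Tmem221, Olfr180, Mroh6, Gm13259, Gm19097, Gm49132 and Gm49756 in 3 or fewer. Of the 24, 19 had a mean under 1 CPM, where 8747 genes were tested, and 4 a mean between 1 and 10 CPM, where 7707 were tested. Stat2 was the 1 call among 8494 genes with a mean of 10 CPM or more. Dpys, Kctd11, Adprhl2, Prdm14, Mroh6, Gm13333, Gm19097 and Gm49132 lie on the same strand within 20 kb past the end of a more highly expressed gene.

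The number of calls depended on the tool and on single libraries. DESeq2 called 307 genes higher and 41 lower, and limma voom 124 and 29. The count of higher genes was 12 without 33 °C replicate 1, 10 without 33 °C replicate 4, 15 without 42 °C replicate 1 or 4 and 14 without 42 °C replicate 2 or 5, and 13 of the 24 genes were also called without 42 °C replicate 2. Slmapos2 lost its call in each of the 10 fits that left out 1 library (edgeR adjusted p up to 0.110). Stat2 lost it without 33 °C replicate 2 (edgeR adjusted p = 0.0565) or without any 1 library at 42 °C (edgeR adjusted p up to 0.108), and by limma voom (log2 -3.15, adjusted p = 0.135, from 8.60e-09 to 0.207 over all alternatives). Prdm14 and Kctd11 lost theirs without 33 °C replicate 1 (edgeR adjusted p = 0.0590 each) or 33 °C replicate 4 (edgeR adjusted p = 0.0544 each).

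Among 34 tested heat shock chaperones and co-chaperones, Hspa1a rose and 33 did not pass the test. Hspa1b (ENSMUSG00000090877, chromosome 17, 34956436 to 34959238), the second gene of inducible HSP70, had 2.40 ± 1.06 CPM at 33 °C and 6.45 ± 3.16 CPM at 42 °C. Its log2 fold change was 1.43 (SE 0.36, edgeR adjusted p = 0.262 over all features), and it passed when adjusted over the list alone (edgeR adjusted p = 0.0286) and with DESeq2 (adjusted p = 0.00854, from 0.00190 to 0.581 over all alternatives). Adjusted over the list alone, 2 members rose and 0 fell. Hspa1a and Hspa1b are near-identical, so the division of reads between them is uncertain. Their sum was 2.68 ± 1.14 CPM at 33 °C and 8.58 ± 4.20 CPM at 42 °C, with no overlap, a ratio of 3.20 and an exact permutation p of 0.00794, the smallest that test can give. Hsph1, the HSP110 chaperone, had a log2 fold change of 0.22 (95% interval -0.00 to 0.43), the constitutive chaperone Hspa8 of 0.09 (-0.19 to 0.37) and the co-chaperone Dnajb1 of -0.24 (-0.55 to 0.08). Ahsa1, a cofactor of HSP90, had -0.30 (SE 0.15). None of these 4 passed the test. The list as a set did not pass (camera adjusted p = 0.413, median -0.11 and mean 0.05). The 18 tested testis-enriched chaperones and heat shock factors did not pass either (camera adjusted p = 0.615), and passed as higher with limma voom without 42 °C replicate 2 (median 0.19, 0.0176). Their member of smallest p was the heat shock factor Hsf1, at -0.28 (SE 0.11).

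**Figure D2:**
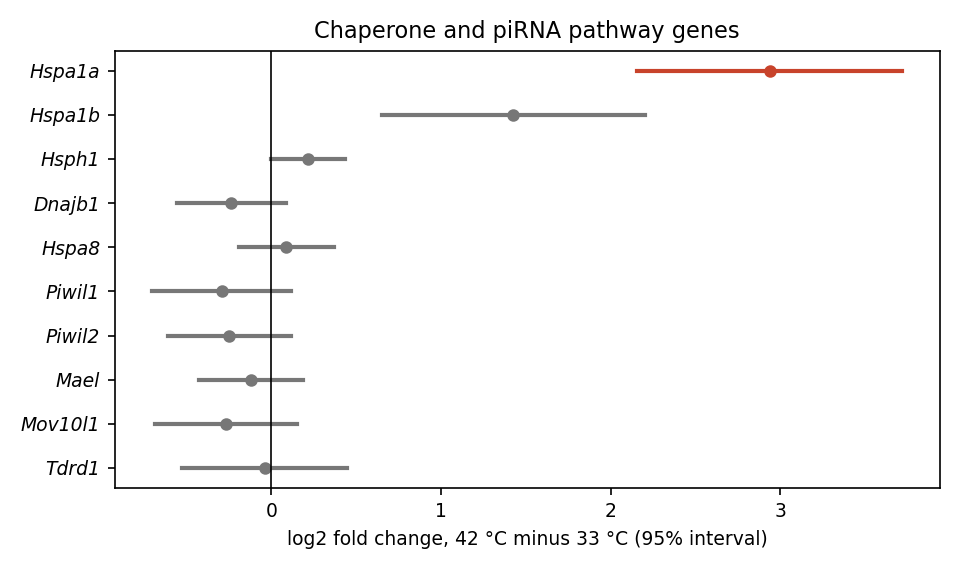
Log2 fold change, 42 °C minus 33 °C (horizontal axis), of 5 chaperone genes and 5 piRNA pathway genes, with 95% intervals of the edgeR fit over 10 libraries. Hspa1a, in red, is the 1 gene of the 10 that passed the threshold over all features, at 2.94.

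Genes of the piRNA pathway, which makes the small RNAs that silence TE in germ cells, were slightly lower at 42 °C as a group at the preset correlation (camera adjusted p = 0.0182), and not with an estimated one (0.803) or by fry (0.452). None of the 31 tested genes passed the test alone. Markers of spermatocytes, an earlier germ cell stage, were lower by a similar amount (median -0.15, camera adjusted p = 0.0423, and 0.803 with an estimated correlation). Of the 31, 23 had a negative log2 fold change, with a median of -0.14. Exd1 had -0.35 (SE 0.13), Mybl1, a transcription factor of pachytene piRNA clusters, had -0.44 (SE 0.18), Pnldc1, the trimming enzyme, had -0.40 (SE 0.18) and the methyltransferase Henmt1 had -0.27 (SE 0.14). Piwil1 (MIWI) had 178 ± 35.5 CPM at 33 °C and 145 ± 37.3 CPM at 42 °C, with a log2 fold change of -0.29 (95% interval -0.70 to 0.12). Piwil2 (MILI) had -0.25 (-0.61 to 0.11), Mov10l1 had -0.27 (-0.69 to 0.15), Mael had -0.12 (-0.43 to 0.19) and Tdrd1 had -0.04 (-0.53 to 0.45). Without 42 °C replicate 2 the values were 0.0095 for Mael, -0.25 for Tdrd1, -0.42 for Piwil1, -0.32 for Piwil2 and -0.31 for Mov10l1. Without that library the list kept its call on the edgeR values (median -0.086, camera adjusted p = 0.0440) and lost it with limma voom (median -0.048, 0.0898). It also lost its call without 33 °C replicate 2 (camera adjusted p = 0.156), with limma voom on all libraries (adjusted p = 0.0670), with a mean of at least 1 CPM (0.0533) or with the log ratio of TE to gene counts as a covariate (0.0831). Over all alternatives the adjusted p was 0.00868 to 0.803. Adjusted over the list alone, 0 members passed. The 32 tested repressors of TE that act on chromatin or RNA did not pass (camera adjusted p = 0.0749, median -0.13), with Ehmt1 at 0.55 (SE 0.23).

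Subfamilies of TE were slightly higher at 42 °C in 6 of 13 groups at the preset correlation, and in 0 with an estimated one (adjusted p = 0.803 for each of the 6). Of 100 splits of the 10 libraries into 5 and 5, 75 gave at least as many called TE lists, the real one included, so chance cannot be excluded. The 6 calls were lost without 42 °C replicate 2 and turned to lower for L1 and DNA transposons with limma voom. TE took 6.84 ± 1.99% of counts at 33 °C and 8.51 ± 4.34% at 42 °C (SD, n = 5 each), a difference within the spread (exact permutation p = 0.579). L1 took 1.84 ± 0.614% and 2.30 ± 1.44% (exact permutation p = 0.706), and the 6 young L1 subfamilies took 0.573 ± 0.169% and 0.700 ± 0.420% (exact permutation p = 0.738). In 42 °C replicate 2 the shares were 16.2% for TE and 4.84% for L1, and in the other 4 libraries at 42 °C they were at most 7.30% and 1.92%. Without it TE took 6.59 ± 0.823% at 42 °C (n = 4), which was 0.244 percentage points under the 33 °C mean (difference -0.244, exact permutation p = 0.833). Of the 9 shares compared, SINE took 2.41% and 3.06%, LTR elements 1.86% and 2.34%, LINE 1.98% and 2.48%, DNA transposons 0.256% and 0.316%, satellites 0.0399% and 0.0498%, and IAP 0.0718% and 0.109%. All 9 had an adjusted permutation p of 0.738.

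**Figure D3:**
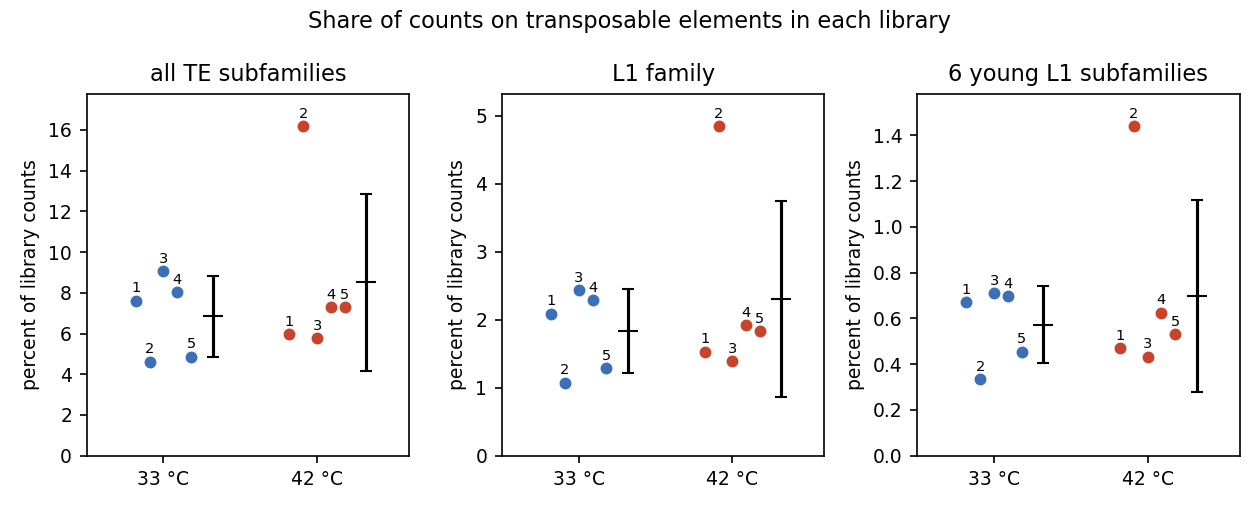
Share of each library's counts, in percent, on all TE subfamilies, on the L1 family and on 6 young L1 subfamilies at 33 °C and 42 °C. Points are libraries with their replicate numbers, and the bar is the mean ± SD of 5. Replicate 2 at 42 °C is the highest of the 10 in all 3 panels, at 16.2%, 4.84% and 1.44%.

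No single TE subfamily passed the test. edgeR called 0 of 1077 higher and 0 lower at 42 °C, with 29 higher and 0 lower at an unadjusted p under 0.05, where chance gives 53.9 in both directions together. These counts were 14 higher and 21 lower with limma voom, 7 and 5 with edgeR without 42 °C replicate 2, and 11 and 56 with limma voom without it. limma voom called 0, and DESeq2 called 1, LTR9A1 (log2 1.82, DESeq2 adjusted p = 0.00604, from that value to 0.621 over all alternatives). Of 30 splits of the libraries into 5 and 5, 4 gave at least 1 subfamily with DESeq2, the real one included. LTR9A1 was also the subfamily of smallest p in edgeR, with 0.0747 CPM at 33 °C and 0.267 CPM at 42 °C (edgeR adjusted p = 0.132). The next ones higher were MamRep1894 (log2 1.49), RLTR50A (1.08), LTR108c_Mam (1.12) and MER58D (0.60), and those lower were MLTR18B_MM (-0.23), LTR86A2 (-0.60), RLTR1D2_MM (-0.19), UCON23 (-0.45) and RLTR6_Mm (-0.19), none past the threshold. Without 42 °C replicate 2 RLTR50A had 0.63, LTR108c_Mam 0.66 and LTR86A2 -1.0. Of the young L1 subfamilies, L1Md_A had 799 ± 215 CPM at 33 °C and 956 ± 521 CPM at 42 °C, and the 95% interval of its fold was 0.756 to 1.89. The interval was 0.735 to 1.66 for L1Md_T, 0.776 to 1.64 for L1Md_Gf, 0.786 to 1.84 for L1Md_F, 0.746 to 1.96 for L1Md_F2 and 0.744 to 1.86 for L1Md_F3. Without 42 °C replicate 2 all 6 had a log2 fold change under 0, from -0.15 for L1Md_T to -0.05 for L1Md_Gf. The 6 together did not pass as a set (camera adjusted p = 0.450, median 0.25). Their median was -0.10 without 42 °C replicate 2 (camera adjusted p = 0.479), and -0.22 with limma voom, which gives each library a quality weight (camera adjusted p = 0.200). With limma voom and without 42 °C replicate 2 the median was -0.30 and the set passed as lower (camera adjusted p = 0.0190), the smallest over all alternatives, whose adjusted p reached 0.998.

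Of the 13 TE lists, 6 were higher at 42 °C at the preset correlation and 0 were lower, and none of the 6 passed with an estimated correlation (adjusted p = 0.803 for each). The median log2 fold change was 0.30 for the L1 family (camera adjusted p = 0.00231), 0.30 for ERVK (2.05e-05), 0.25 for ERVL with ERVL-MaLR (0.000563), 0.26 for ERV1 (0.00246), 0.41 for IAP (0.00144) and 0.26 for DNA transposons (0.00231). The other lists did not pass: the camera adjusted p was 0.0590 for B1 SINEs, 0.0733 for B2, 0.315 for B4, 0.0798 for ETn and MusD, 0.110 for MERVL and 0.424 for satellites. Adjusted over the list alone, LTR9A1 passed within ERV1 and 0 members passed in the other 12 lists. Without 42 °C replicate 2, camera on the edgeR values called 0 TE lists in either direction, and the median was -0.07 for L1 (camera adjusted p = 0.183), 0.014 for ERVK (0.996) and 0.14 for IAP (0.306). Leaving out 33 °C replicate 5 also ended the 6 calls (camera adjusted p from 0.112 to 0.440), and 33 °C replicate 2 ended all of them but ERVK (from 0.0561 to 0.312). With limma voom the L1 family (median -0.15, camera adjusted p = 0.0123) and DNA transposons (-0.14, 0.0200) passed as lower instead, and the other 4 lost their calls (0.0670 to 0.571). With limma voom and without 42 °C replicate 2, the TE lists that passed as lower were young L1, as given above, L1 (-0.23, camera adjusted p = 3.33e-08), ERVK (-0.13, 0.000280), ERVL with ERVL-MaLR (-0.16, 1.51e-05), ERV1 (-0.14, 0.00347), DNA transposons (-0.22, 5.30e-07) and B1 SINEs (-0.16, 0.0271). Of the lists that did not pass, B1 SINEs passed as higher without 33 °C replicate 1 (0.0180), 3 (0.0148) or 4 (0.00820) or 42 °C replicate 1 (0.0171), 3 (0.00943), 4 (0.0187) or 5 (0.0427). B2 did so without 33 °C replicate 1 (0.0259), 3 (0.0402) or 4 (0.0427) or 42 °C replicate 1 (0.0141) or 4 (0.0408), ETn and MusD without 33 °C replicate 1 (0.0258) or 4 (0.0414) or 42 °C replicate 4 (0.0341) or 5 (0.0427), and MERVL without 33 °C replicate 4 (0.0414) or 42 °C replicate 3 (0.0389). With no filter on low counts B1 (0.0189), B2 (0.0279), ETn and MusD (0.0373) and MERVL (0.0459) passed as higher, as did B1 with the size factors of DESeq2 (0.0478), DESeq2 itself (0.0409) and a mean of at least 1 CPM (0.0479). With 42 °C replicates 1 and 3 summed B1 (0.0128), B2 (0.0266) and MERVL (0.0435) passed as higher.

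Markers of elongating spermatids, a later stage, and of round spermatids, the cells isolated here, were higher at 42 °C as groups at the preset correlation. The camera adjusted p was 0.00231 for elongating and 0.0150 for round spermatids, and 0.803 for each with an estimated correlation, while no single marker passed the test. Of 30 markers of elongating spermatids 24 had a positive log2 fold change, with a median of 0.33. The mitochondrial capsule gene Smcp had 0.53 (SE 0.21), Ccin, a protein of the sperm head cytoskeleton, had 0.62 (SE 0.25), the protamine family gene Prm3 had 0.61 (SE 0.25) and Spaca9 had 0.45 (SE 0.21). Of 38 round spermatid markers 28 were positive, with a median of 0.26. Cypt1 had 0.50 (SE 0.21), Tex29 had 0.70 (SE 0.29), Fhl5 had 0.56 (SE 0.24) and the kinase Tssk3 had 0.29 (SE 0.14). Of 33 spermatocyte markers 22 were negative, with a median of -0.15, and the examples were Terb1 at -0.31 (SE 0.13), the kinase Nek2 at -0.41 (SE 0.18), securin (Pttg1) at -0.33 (SE 0.15) and Syce2 at 0.48 (SE 0.23).

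The spermatocyte markers passed the set test as lower (camera adjusted p = 0.0423) and did not with an estimated correlation (0.803). The call for elongating spermatids was lost without 42 °C replicate 5 (camera adjusted p = 0.0613), and that for round spermatids without 33 °C replicate 3 (0.172) or 4 (0.125) or 42 °C replicate 4 (0.151). The call for spermatocytes was lost without 33 °C replicate 2 (0.165), 3 (0.0508) or 5 (0.112) or 42 °C replicate 2 (0.182), 4 (0.0992) or 5 (0.0540). It was also lost with scaling from genes only (0.0546), library totals (0.0652), DESeq2 (0.0520), limma voom (0.524) and a mean of at least 1 CPM (0.0953). Adjusted over the list alone, 0 members of the 3 lists passed.

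Markers of spermatogonia, the mitotic germ cells, were higher as a group, with 14 of 19 tested markers positive and a median of 0.08 (camera adjusted p = 0.0371, and 0.803 with an estimated correlation). Cdh1 had 0.402 ± 0.135 CPM at 33 °C and 0.855 ± 0.259 CPM at 42 °C (log2 1.09, SE 0.28), Pou5f1 had a log2 fold change of 0.87 (SE 0.24), Prss50 of 1.21 (SE 0.39) and the receptor Kit of 0.71 (SE 0.29). Adjusted over the list alone, Cdh1 and Pou5f1 rose (edgeR adjusted p = 0.0341 each) and 0 fell, and over all features none of the 19 passed. It lost its call without 33 °C replicate 2 (camera adjusted p = 0.103) or 5 (0.112) or 42 °C replicate 1 (0.0656) or 3 (0.0528), and with no filter on low counts (0.0681), with 42 °C replicates 1 and 3 summed (0.0532) or with the log ratio of TE to gene counts as a covariate (0.0877). Without 42 °C replicate 2 its median was 0.21 (0.0440).

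Sertoli cell markers, which trace the somatic cells of the tubule, had a median of 0.30 and missed the threshold (camera adjusted p = 0.0631). They passed as higher without 42 °C replicate 2 (camera adjusted p = 0.0300), 33 °C replicate 1 (0.0259) or 3 (0.00336) or 42 °C replicate 4 (0.0408), and with no filter on low counts (0.0459), with Cst9 of smallest p at 0.186 and 0.489 CPM. Leydig cell markers had a median of -0.62 (camera adjusted p = 0.107) and passed as lower with DESeq2 (0.0251), with no filter on low counts (0.0459) and without 33 °C replicate 1 (0.0180) or 4 (0.00115) or 42 °C replicate 4 (0.0315) or 5 (0.0153), but without 33 °C replicate 3 their median was 0.17 (0.623), with Scarb1 of smallest p at a log2 fold change of 0.45. Markers of peritubular and stromal cells (camera adjusted p = 0.450, Cnn1 0.99), of macrophages and leukocytes (0.917, Il1b 0.78) and of endothelium (0.166, Cdh5 0.88) did not pass, though endothelium passed as higher with a mean of at least 1 CPM (median 0.38, 0.0385). Of the erythroid list 1 member was tested, Alas2, at no more than 0.289 CPM, so that list has no set test.

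Proteasome subunits, oxidative phosphorylation, the unfolded protein response, ribosomal proteins and RNA granule proteins were lower at 42 °C as groups by small amounts. In these 5 lists 0 members passed the test, and the calls hold at the preset correlation alone (camera adjusted p = 0.803 for each with an estimated correlation). Of 100 splits of the libraries, 68 gave at least as many called lists as the real 16, the real one included, so chance cannot be excluded. Proteasome subunits had 29 of 32 negative and a median of -0.16 (camera adjusted p = 0.000759), with the testis subunit Psma8 at -0.78 (SE 0.35), Psmd3 at -0.32 (SE 0.16), Psmb4 at -0.25 (SE 0.13) and Psmb3 at -0.20 (SE 0.12). Nuclear genes of oxidative phosphorylation had 69 of 84 negative and a median of -0.09 (0.00679), with Atp5pb at -0.31 (SE 0.11), Ndufa11b at 0.67, Atp5mpl at 0.41 and Ndufs1 at -0.29. Genes of the unfolded protein response had 22 of 28 negative and a median of -0.20 (0.0201), with the sensor Ern1 at 0.60 (SE 0.18), Asns at 0.60 (SE 0.25), the chaperone Hsp90b1 at -0.39 (SE 0.18) and Ppp1r15a at -0.90 (SE 0.40, and -0.34 without 33 °C replicate 3). Cytosolic ribosomal proteins had 70 of 82 negative and a median of -0.07 (0.0323), with Rpl39 at 1.02, Rpl30 at -0.34, Rpl6l at 0.47 and Rpl10a at -0.34. RNA granule proteins had 22 of 28 negative and a median of -0.16 (0.0371), with the helicase Ddx3x at 0.83 (SE 0.32), Edc4 at -0.33 and G3bp2 at -0.26.

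All 5 lost the call without 42 °C replicate 2, where the medians were -0.06 for proteasome subunits (camera adjusted p = 0.182), 0.014 for oxidative phosphorylation (0.960), -0.13 for the unfolded protein response (0.181), 0.05 for ribosomal proteins (0.422) and -0.05 for RNA granule proteins (0.345). All but proteasome subunits also lost it without 33 °C replicate 2 or 5 (camera adjusted p from 0.0844 to 0.393), and RNA granule proteins without 42 °C replicate 4 (0.0659). With limma voom the ribosomal proteins passed as higher instead (median 0.070, camera adjusted p = 0.0381), and the other 4 lists lost their calls (0.297 to 0.427). With limma voom and without 42 °C replicate 2, ribosomal proteins (median 0.13, camera adjusted p = 3.30e-06) and oxidative phosphorylation (0.077, 0.00612) passed as higher. Ribosomal and RNA granule proteins also lost theirs with scaling from genes only (0.0660 and 0.0546), library totals (0.0652 and 0.0574), DESeq2 (0.0589 and 0.0531) and a mean of at least 1 CPM (0.0953 and 0.0815), as did the unfolded protein response with that mean (0.102).

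**Figure D4:**
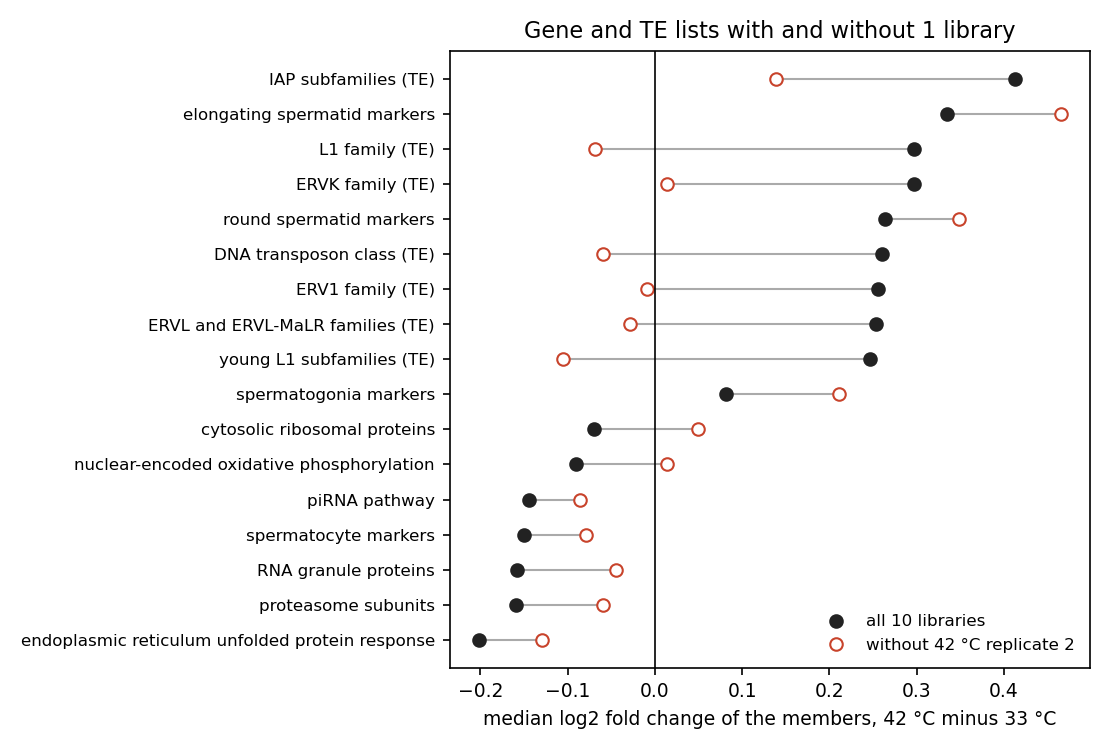
Median log2 fold change, 42 °C minus 33 °C (horizontal axis), of the 16 lists called at the preset correlation and of the young L1 subfamilies. Filled points use all 10 libraries, and open points leave out 42 °C replicate 2. The L1 family moves from 0.30 to -0.07, and elongating spermatid markers from 0.33 to 0.46.

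The remaining lists did not pass the set test. Immediate-early genes, the transcription factors and regulators induced within minutes of stimulation, had a median of -0.20 (camera adjusted p = 0.0571) and 0 of 25 members passed, with Egr3 of smallest p at 27.1 ± 8.21 CPM at 33 °C and 47.5 ± 14.7 CPM at 42 °C (log2 0.81, SE 0.24). As a set they passed as lower with the size factors of DESeq2 (camera adjusted p = 0.0428), with DESeq2 itself (0.0165), with no filter on low counts (0.000669), with the replicate number as a block (0.0365) and without 33 °C replicate 1 (0.0217) or 4 (0.00161) or 42 °C replicate 4 (0.0187) or 5 (0.0217). Without 33 °C replicate 3 the median was -0.042 (0.309), and over all alternatives the adjusted p was 0.000669 to 0.849. The interferon and nucleic acid sensing genes held Stat2 as the 1 of 17 members that fell, over all features and adjusted over the list alone, while Ddx58 had 0.70 (SE 0.23), Irf9 had -0.59 (SE 0.34) and Mx1 had 0.41 (SE 0.25). That list had a camera adjusted p of 0.450, and passed as lower without 33 °C replicate 1 (0.0345). The camera adjusted p was 0.409 for p53 targets (Rrm2b 1.03, SE 0.28), 0.127 for apoptosis machinery (Htra2 -0.37), 0.972 for antioxidant and metal response (Srxn1 0.64), 0.450 for SR splicing factors and CLK kinases (Srpk2 0.40), and 0.243 for replication-dependent histones (H2bc4 0.62). For mitochondrially encoded genes it was 0.844 (mt-Atp8 0.49, and -0.029 without 42 °C replicate 4). Without that library the list passed as lower (median -0.31, camera adjusted p = 0.0168), and without 33 °C replicate 3 its median was 0.27 (0.244). In the antioxidant list the median was -0.02 and the mean 0.10, and in the mitochondrial list the median was 0.01 and the mean -0.02, so that the sign differs between the measures. With the log ratio of TE to gene counts as a covariate, 2 lists were higher, the round and elongating spermatid markers, and 0 were lower. Of the 39 lists tested without it 9 were higher and 7 lower, and 0 were called with an estimated correlation or by the direction test of fry, whose smallest adjusted p was 0.0660, for the spermatogonia markers. The mixed test of fry called 2 lists, the spermatogonia markers (adjusted p = 0.0227) and the interferon list (0.0384).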

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

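The 3 tests of the TE share of 42 °C replicate 2 were chosen after that share was seen. A library stood apart from its group where its gap to the nearest of the other 4, as a part of the group's whole range, was above 0.71, Dixon's limit for 5 samples. This held for 29 of 235 groups of 5 values, where chance gives 11.8, with 22 at 42 °C and 7 at 33 °C. Many of these groups share reads, as the TE shares and the L1 subfamilies do, so 29 against 11.8 is not a test of an excess. In 19 of the 29 the library apart was 42 °C replicate 2. It had the highest share of counts on TE (ratio 0.854, 16.2% against a next highest of 7.30%), L1 (0.848), young L1 (0.808), LINE (0.849), SINE (0.822), LTR elements (0.844), DNA transposons (0.857) and IAP (0.80). It was also highest for L1Md_A (0.783), L1Md_F2 (0.793), L1Md_F3 (0.819), L1Md_F (0.798), L1Md_T (0.713), LTR108c_Mam (0.858), LTR86A2 (0.778), Mroh6 (0.847) and Tdrd1 (0.732, 80.1 against 46.2 CPM). It was lowest for Mael (0.756, 860 against 1210 CPM) and in total counts (0.726).

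The other 10 groups had another library apart. 33 °C replicate 2 was highest in total counts (0.885) and lowest for L1Md_Gf (0.719) and MER58D (0.714). 33 °C replicate 3 was highest for Dpys (0.822, with 5 of the 6 counts of its group), Gm49132 (0.844), Ppp1r15a (0.793) and Rpl39 (0.733). 42 °C replicate 4 was highest for mt-Atp8 (0.848, 182 against 65.3 CPM), Tex29 (0.723) and Syce2 (0.759). No explanation was tested for these 10.

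For the TE share of 42 °C replicate 2, genomic DNA as the source of all the excess is argued against, since 53.9% of 2102 olfactory, vomeronasal, defensin and keratin-associated genes had 0 counts in it (95% interval 51.7 to 56.0), where the excess spread over the genome as DNA leaves 8.53% at 0. In the other 9 libraries 58.7% to 65.1% of these genes had 0 counts, so the families are not without reads there either. They took 663 CPM in 42 °C replicate 2 and 207 to 348 CPM in the other 9, so a smaller amount of DNA stays open. Intronic RNA cannot be told apart, because the TE share correlated with the share of counts on sense intronic genes over the 10 libraries at a Spearman rho of 0.527 (permutation p = 0.123) and a Pearson r of 0.907 (permutation p = 0.00779), but with r at 0.590 without the 2 libraries farthest out (permutation p = 0.124). A response to heating shared by the group is argued against, since the other 4 libraries at 42 °C had a mean TE share lower than the 33 °C mean (difference -0.244 percentage points, 33 °C SD 1.99). A response of that 1 mouse to heating stays open, and so may a difference in its cells or RNA.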

How the results depend on the processing

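Of the alternatives, 5 were chosen after the data were seen: DESeq2 and limma voom on 9 libraries (42 °C replicate 2 left out), the log ratio of TE to gene counts as a covariate, the robust quasi-likelihood fit, and 42 °C replicates 1 and 3 summed as 1 library. All alternatives that were planned were run, except that the minimum fold of 1.2 was applied to single features and gives no value for a list. Where a cause is not named below, the cause was not tested.

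Over all alternatives, values of the called genes had the same direction and call in 419 cases, lost the call in 161 and turned in 0. For the lists the direction and call were the same in 788 cases, a call was gained in 52, lost in 114 and the direction turned in 33. Other named genes gained a call in 5 cases and were the same in 1684, and TE subfamilies gained one in 2 and were the same in 391.

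The count of genes higher at 42 °C, 23, was 15 with library totals, 307 with DESeq2, 124 with limma voom, 73 with no filter on low counts, 2 among genes with a mean of at least 1 CPM, 190 with DESeq2 on 9 libraries, 83 with limma voom on 9 libraries, 40 with the covariate and 10 to 21 on leaving out each library. The count of genes lower, 1, was 41 with DESeq2, 29 with limma voom, 3 with no filter, 0 with a mean of at least 1 CPM, 58 with DESeq2 on 9 libraries, 28 with limma voom on 9 libraries, 3 with the covariate, 0 with 42 °C replicates 1 and 3 summed and 0 to 2 on leaving out each library. TE subfamilies higher numbered 1 with DESeq2 on 10 or on 9 libraries, and 0 in every fit with edgeR or limma voom. In the edgeR test of all libraries 29 subfamilies were higher and 0 lower at an unadjusted p under 0.05, against 34 and 53 with the covariate.

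The replicate number as a block left 4 genes higher and 0 lower (edgeR), and limma voom without the block called 124 and 29, DESeq2 307 and 41. The numbers give no sign of pairing the libraries, since the correlations between libraries of the same number were -0.411 to -0.122 and 0 of 5 libraries at 33 °C correlated best with its own number.

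Lists higher at 42 °C, 9, were 4 with limma voom, 4 with DESeq2 on 9 libraries, 2 with the covariate, 0 with an estimated correlation, 0 by fry and 2 to 13 on leaving out each library. Lists lower, 7, were 4 with scaling from genes only, 4 with library totals, 2 with limma voom, 2 with a mean of at least 1 CPM, 1 with DESeq2 on 9 libraries, 0 with the covariate, 0 with an estimated correlation, 0 by fry and 1 to 10 on leaving out each library.

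For lists whose direction turned in the test, medians are given as log2 fold changes, in the order limma voom, DESeq2 on 9 libraries, limma voom on 9 libraries and the covariate. They were -0.22, -0.12, -0.30 and -0.089 for young L1 (-0.10 to 0.37 on leaving out each library), -0.15, -0.083, -0.23 and -0.054 for L1 (-0.068 to 0.42), -0.10, -0.041, -0.16 and -0.025 for ERVL with ERVL-MaLR (-0.028 to 0.36), -0.14, -0.076, -0.22 and -0.047 for DNA transposons (-0.060 to 0.38) and 0.070, 0.028, 0.13 and 0.0069 for ribosomal proteins (-0.12 to 0.050). With limma voom, DESeq2 on 9 libraries and limma voom on 9 libraries they were -0.071, 0.0029 and -0.13 for ERVK (0.014 to 0.40 on leaving out each library, where the median stays above 0, as it does with DESeq2 on 9 libraries, while the direction of the test turned) and -0.073, -0.020 and -0.14 for ERV1 (-0.0094 to 0.36). With limma voom on 10 and on 9 libraries they were 0.016 and 0.077 for oxidative phosphorylation. With limma voom on 9 libraries alone they were 0.014 for proteasome subunits, -0.023 for IAP and -0.16 for B1. On leaving out each library the difference in TE share was -0.244 to 2.35 percentage points and that in L1 share -0.168 to 0.694. In limma voom the weights lower the part of libraries far from the fit, and on 9 libraries the library of the highest TE share is absent by construction.

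Depth limits the genes of low level. With a mean under 1 CPM the median SE of a log2 fold change was 0.35, against 0.15 at 10 CPM or more, and 19 of the 24 called genes lay there.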

Other observations

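The tests of the placement of low genes, and of its dependence on 42 °C replicate 2, were chosen after the placement was seen. The 24 genes called by edgeR, Dpys, Hspa1a and Stat2 among them, exceed every other split of the 10 libraries drawn. Of 100 splits into 5 and 5, 1 gave as many, the real one, and the highest of the others gave 9. Chance is thus argued against for this count, as far as 100 splits can show. For the 348 genes called by DESeq2, 30 splits were drawn, and chance cannot be excluded at that number, since 2 of the 30 gave as many, the real one and 1 other with 2169. That other split set 33 °C replicates 2 and 5 and 42 °C replicates 1, 3 and 4 against the rest, and a count this far above the real one points to a structure of the samples. Principal components were computed from the log2 CPM of the features of largest variance, genes and TE together. The first (23.5% of the variance of these features) parts the temperatures, with -29.2 to -7.08 at 33 °C and 9.61 to 32.1 at 42 °C. The second (21.9%) parts the libraries in the same way as that split, with -27.2 to -1.02 on that side and 8.39 to 28.3 on the other. The 4 libraries with the lowest TE shares, 4.62% to 5.98%, are all on the first side. For the 0 TE subfamilies called by edgeR (29 at an unadjusted p under 0.05, and 1 by DESeq2 and 0 by limma voom adjusted) the splits say nothing, since any split gives at least 0, here 100 of 100 with a highest other of 0. For the 1 subfamily called by DESeq2 chance cannot be excluded, since 4 of 30 splits gave as many, the real one included, and the highest other gave 548. Chance cannot be excluded for the 16 lists called, where 68 of 100 splits gave as many, and the other splits had a median of 19 and a highest of 30. Nor can it for the 6 TE lists among them, where 75 of 100 gave as many, and the other splits had a median of 10 and a highest of 13.

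Of the genes past the threshold, 5 lie on chromosome 15, which holds 3.86% of the tested genes: 4930555K19Rik, Dpys, Apol9a, Naprt and Mroh6. They were chosen after their values were seen. Mroh6 (75884137 to 75888770) and Naprt (75890956 to 75894481) lie close together on the same strand, so their calls may not be independent.

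Genes of low level that were higher at 42 °C often lay just past a more highly expressed gene. Called genes that overlap a gene of at least 10 CPM, as Naprt does, were given no placement and stay among the 21 below. Of the 21 called genes under 2 CPM, 8 lay on the same strand within 20 kb past a gene of at least 10 CPM: Kctd11 0.161 kb past Acap1, Adprhl2 0.418 kb past Tekt2, Mroh6 5.43 kb past Eef1d, Gm19097 8.19 kb past 1700109G14Rik, Gm13333 8.57 kb past Spag6, Gm49132 10.5 kb past Samd4, Prdm14 11.9 kb past Ncoa2 and Dpys 13.1 kb past Lrp12. Among tested genes under 2 CPM that lie within 20 kb of a gene of at least 10 CPM, the called genes left out, 71 of 868 in this placement were higher at an unadjusted p under 0.01 (8.18%, 95% interval 6.44 to 10.2), against 55 of 1997 upstream of the expressed gene or on the other strand (2.75%), while 0.346% and 0.401% were lower.

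A candidate explanation is transcription that runs past the ends of upstream genes, and the difference of 5.43 percentage points goes with it. The library 42 °C replicate 2 is argued against as the source, since the difference without it was 4.64, and so is a higher level of the upstream genes, whose median log2 fold change was 0.075 (quartiles -0.11 to 0.28, 0 of 71 at 1 or more) where the genes past them had 1.40. More unspliced RNA at 42 °C cannot be told apart, since 8 of 167 sense intronic genes were higher (4.79%, 95% interval 2.09 to 9.22), which spans the 8.18% above. Of 100 splits drawn, 2 gave as large a difference, the real one and 1 other with 8.70. That lies under the limit of 0.05 of the splits, though the same 2 among 30 drawn would not. Since the other split gave more than the real one, chance is not excluded for the difference. The other is the split of 2169 DESeq2 calls above, which mixes the temperatures, so the placement differs more along that structure of the samples than between 33 °C and 42 °C, and heating as its source stays open. Whether the reads are joined to the upstream transcripts was not tested.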
